A study of Homo sapiens with 6 samples.

How the data were processed

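Gene expression was measured in CD8+ T cells from tumour-infiltrating lymphocytes of human lung cancer. Per the labels and the series' design text, the lymphocytes were grown for 20 days with recombinant interleukin-2 alone or with interleukin-2 and interleukin-10, restimulated for 6 h with antibodies to CD3 and CD28 at 3 µg/ml, and enriched for CD8+ cells by negative selection. The labels give doses of 6000 for interleukin-2 and 100 for interleukin-10 per ml in a unit that is not clear from them, so the doses are given without a unit. Each of the 2 groups has 3 arrays, numbered 1 to 3. The groups are called IL-2 and IL-2 + IL-10.

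The arrays were 1-colour Affymetrix arrays with 22277 probe sets. The deposited values are on the log2 scale. Per the submitters' processing notes, the authors used Partek 6.6 and RMA. The background step, the chip definition and any filter are not given in the sources used here. The medians of the 6 arrays lay between 6.24 and 6.28. RMA values of weakly expressed genes are known to be compressed, so their differences can be understated. Array values carry no read depth, and the number of arrays limits the precision.

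Probe sets were named from the platform annotation, with symbols checked through Entrez identifiers against the RefSeq gene table of GRCh38.p14, which was used for names only. Of the 22277 probe sets, 19070 had 1 gene symbol, 1043 had several and 2164 had none, and 62 of all sets were array controls. The identifier was found for 19058 of the sets with 1 symbol, and the other 12 kept their listed symbol. The 11963 genes were each represented by the probe set with the highest mean over all 6 arrays, and 4310 genes had more than 1 set. A gene was tested if this probe set was above the 40th percentile of its array on at least 3 arrays, which left 7983 genes.

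Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with the Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The main model held the group alone. The same model with the number as a block was an alternative. The numbers come from the sample titles, which do not say that a number is a donor. The check for pairing, with its rule of a correlation over 0.1 in every pair, took the correlation across genes of each array's deviations from its group mean. It was 0.72, 0.49 and 0.36 for arrays with the same number and between -0.56 and 0.20 for arrays with different numbers, so the numbers were taken to pair the arrays. The correlations between arrays of numbers 2 and 3, 0.20 and 0.16, also exceeded 0.1, so the rule alone does not separate these numbers. Deviations from a group mean sum to 0, so the low values for different numbers are not separate evidence. The main model, fixed before this check, leaves the variation between numbers in its error. Its median SE was 0.102, against 0.079 with the block, so the text also gives values with the block. In a check of sex-linked genes for mixed-up samples, 0 of the 3 same-numbered pairs disagreed. This check cannot see a swap between samples of the same sex or an exchange of the 2 treatments within a number. Nothing in the labels says that the 3 arrays of a group came from separate donors or cultures, so p-values measure the spread between these samples, which may be technical in part. No 2 arrays held the same values, the closest pair being IL-2 arrays 2 and 3 with a correlation of 0.995 across genes.

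Before the data were examined, 44 gene lists, the tests, the alternatives, the pairing rule and a rule for the genes to be named were fixed. The lists covered T cell programmes, activation, cytokine pathways, complement, Notch, cell cycle, metabolism, stress and markers of other cells. Lists with at least 4 tested members, 41 in all, were tested with limma's camera at a preset correlation of 0.01 between genes, with the adjustment over the lists. Camera was also run with an estimated correlation. The limma function fry tests whether a list's members move one way, or in its mixed form in either direction, without comparing the list with other genes. The rule named the 12 genes per direction with the largest log2 difference among those past the threshold, the same with the block, up to 4 members per list with the smallest p, and 31 fixed genes. Genes of the sex chromosomes that reveal sex and genes whose level can follow a person's genotype or clones were kept out of it. The rule gave 183 tested genes, all of which went through the alternatives. The text prints part of them, selected after their values were seen.

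The alternatives were the block, no filter, a filter at the 60th percentile, a second quantile normalization, centring on the array median, a floor at the 40th percentile, eBayes with trend and robust, the mean of a gene's probe sets, every probe set as its own row, other thresholds, an unmoderated model, other list tests, lists without shared genes, and leaving out each array or each number. The models were tested on simulated data made from the real means of all 7983 genes and their variances as moderated by limma, with 200 genes changed. Errors were normal, as limma assumes, and were simulated as independent between genes, so the counts below need not hold for the real values. This simulation was written after the models had first been run on the real values. Without the block, 35 of 50 genes changed by 0.5 on the log2 scale were recovered, 48 of 50 at a change of 1, 49 of 50 at 1.5 and 50 of 50 at 2, with 4 false calls among 186. With the block the numbers were 47, 50, 50 and 50 of 50, with 14 false calls among 211. In 20 simulations of independent genes, camera called a list of 12 genes shifted by 0.5 every time and called 1 of 800 unchanged lists. Those genes were simulated without correlation, so this says nothing about camera's error rate in correlated lists. Figures were drawn with matplotlib 3.10.9.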

Results

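CD8+ T cells were profiled on 6 arrays, 3 from lung tumour lymphocytes grown with interleukin-2 (IL-2) and 3 from lymphocytes grown with interleukin-2 and interleukin-10 (IL-2 + IL-10), all restimulated for 6 h through CD3 and CD28. The comparison asks what growth with interleukin-10 does to the transcripts of restimulated tumour T cells, and the series title places it in a study of complement and interleukin-10 in antitumour T cell responses. Values are log2 expression, and differences are IL-2 + IL-10 minus IL-2, so a difference of 1 is a doubling. Means are given ± SD with n = 3 arrays per group, and some differences with their SE.

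With interleukin-10, NF-kB target genes and immediate early genes were lower as groups, and the IL-10 and STAT3 pathway higher, in a list test with a preset correlation. These calls were lost at adjusted p = 0.585, 0.585 and 0.353 with an estimated correlation. By directional fry without the block, the first 2 lists did not pass (adjusted p = 0.158 and 0.196) and the IL-10 and STAT3 pathway did (0.0183). RCAN2, a regulator of calcineurin, rose from 3.99 ± 0.02, a level under the expression filter, to 7.03 ± 0.38 (adjusted p = 0.00235). The size of its rise depends on that low level: it was 3.04 (SE 0.18) as measured and 1.45 with values under the 40th percentile set to that percentile (adjusted p = 0.0213). CD83, an activation marker of lymphocytes and dendritic cells, had the largest fall among genes past the threshold, from 9.32 ± 0.52 to 7.32 ± 0.30, a 4.01-fold lower level (adjusted p = 0.0276). PTGER4, a prostaglandin E2 receptor, fell from 11.25 ± 0.06 to 9.99 ± 0.02 (adjusted p = 0.00235). Of 7983 genes, 88 passed the threshold in the model without the block, 47 higher and 41 lower, and 23 of them differed more than 2-fold. With the number as a block, which takes up the pairing of the arrays, 528 passed.

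Among genes past the threshold, the largest rises beside RCAN2 were in HCRP1 (1.60), the stress-induced mTOR inhibitor DDIT4 (1.59), the complement regulator clusterin CLU (1.41), the tyrosine kinase FES (1.38), the chemokine receptor CCR1 (1.33), the protease FURIN (1.17), STOM (1.10), CYTH4 (1.05), the fatty acid transporter SLC27A2 (1.02), the sphingolipid enzyme KDSR (1.02) and the cytokine signalling inhibitor SOCS3 (1.01). With the mean of its probe sets KDSR did not pass (0.49, adjusted p = 0.0642). Among the same genes, the largest falls after CD83 were in CRTAM (-1.73), a receptor of activated CD8+ T cells, the nuclear receptor NR4A3 (-1.41), PTGER4 (-1.26), the chemokine CCL1 (-1.25), NTRK2 (-1.23), MYBL1 (-1.21), the NF-kB inhibitor TNFAIP3 (-1.18), DIPK1A (-1.13), the survival gene BCL2L1 (-1.04), the fractalkine receptor CX3CR1 (-1.01) and the pro-apoptotic PMAIP1 (-0.96). With values under the 40th percentile set to that percentile, the differences of FES (1.29), SOCS3 (0.83) and NTRK2 (-0.60) were smaller and still passed. That of CCL1 (-0.77) no longer passed (adjusted p = 0.0524). The probe set of DIPK1A is of a kind that can also detect other transcripts. All 88 called genes moved in 1 direction in all 3 numbers, which passing the threshold with 3 arrays per group makes likely. At an unadjusted p under 0.05, 1362 genes differed, 772 higher and 590 lower, against 399.2 expected if no gene differed. The balance turned to 797 higher and 867 lower without IL-2 + IL-10 replicate 3, to 575 and 673 without both arrays of number 3, and to 120 and 132 among genes that differed at least 1.5-fold. Other splits of the 6 arrays into 3 and 3 gave 19 to 964 genes at an unadjusted p under 0.05. The value of 399.2 therefore does not bound what other groupings of these arrays give. With the number as a block, 528 genes passed, 287 higher and 241 lower, and these included all 88. The count of 88 changed when 1 array was left out. It was 66 without IL-2 replicate 1, 41 without IL-2 + IL-10 replicate 1 and 3 without IL-2 replicate 2. It was 0 without IL-2 + IL-10 replicate 2, 4 without IL-2 replicate 3 and 60 without IL-2 + IL-10 replicate 3. Of the 88, 44, 32, 3, 0, 4 and 43 were called again in these settings, in the order given, and none that was still tested changed its direction. By limma without adjustment, 1088 genes had a p under 0.05 without IL-2 + IL-10 replicate 2, and 872 without IL-2 replicate 2.

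Of 41 gene lists tested, 12 passed camera with a preset correlation, 11 of them lower and 1 higher with IL-2 + IL-10, and 7 passed without IL-2 + IL-10 replicate 3. With an estimated correlation 0 passed, the smallest adjusted p being 0.353.

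**Figure D1:**
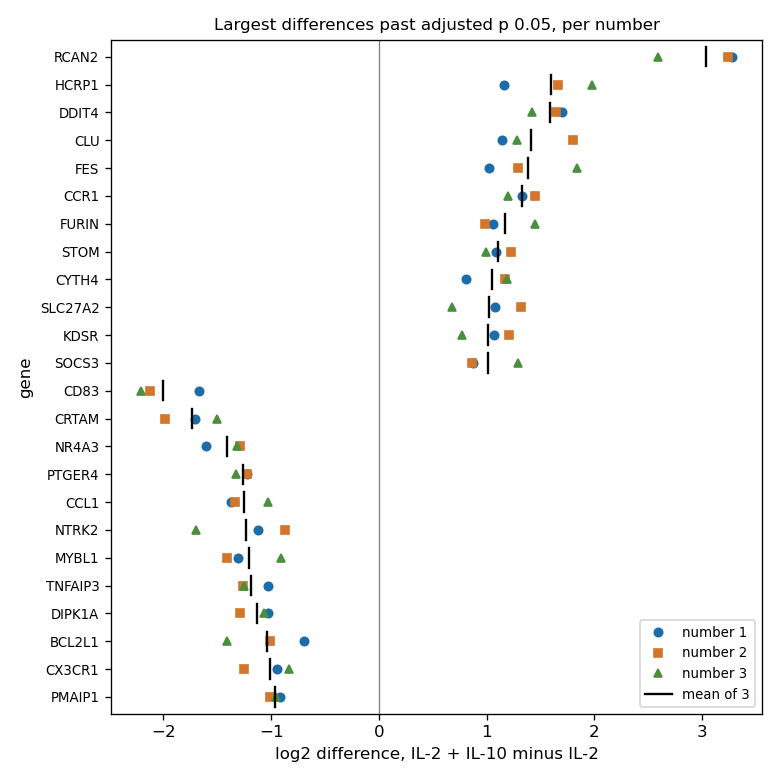
Log2 difference between the IL-2 + IL-10 and the IL-2 array of each number (symbols) and the mean of the 3 (black lines) for the 12 genes per direction with the largest differences past adjusted p 0.05. RCAN2, whose IL-2 level lay under the expression filter, has a mean difference of 3.04 (1.45 with values under the filter level raised to it), and CRTAM has -1.73. All 3 numbers lie on the same side of 0 for each gene, which the selection by adjusted p makes likely.

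NF-kB target genes were lower as a group. Of the list's 18 members, 15 had a probe set with a single gene symbol and were tested. The other members had no such probe set and could not be compared, so their direction is not known. All 15 had lower means, with a median difference of -0.79, and medians of -0.70, -0.66 and -0.81 in the 3 numbers. The list passed camera (adjusted p = 3.67e-10), a call lost at adjusted p = 0.585 with an estimated correlation. Directional fry did not call it without the block (adjusted p = 0.158) and called it with the block (0.0196). CD83, TNFAIP3 and BCL2L1 fell over all genes tested, and 12 members were lower when adjusted over the list alone. With the block, 11 members passed over all genes. REL, a subunit of NF-kB, differed by -1.42 (adjusted p = 0.0718, 0.0339 with the block), and ICAM1, an adhesion molecule, by -0.74 (adjusted p = 0.0772, 0.0156 with the block).

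Immediate early activation genes, those induced first after stimulation, were lower in 20 of 23 members, with a median of -0.29 (camera adjusted p = 0.000169, and adjusted p = 0.585 with an estimated correlation). Without IL-2 + IL-10 replicate 3 the median was -0.18 (adjusted p = 0.0168). Directional fry did not call the immediate early list without the block (adjusted p = 0.196) or with it (0.119). NR4A3 and the early activation marker CD69 (-0.73) fell, and 8 members were lower and 1 higher when adjusted over the list alone. ZFP36, which binds and destabilises cytokine mRNAs, went the other way, at 0.92 (adjusted p = 0.0923, 0.00918 with the block). Apoptosis regulators were lower in 12 of 17 members (median -0.21, camera adjusted p = 0.00451, and adjusted p = 0.353 with an estimated correlation). BCL2L1, which protects from apoptosis, and PMAIP1 and the death receptor FAS (-0.65), which promote it, fell over all genes, and 7 were lower and 2 higher when adjusted over the list alone. Without the genes that other lists also hold, the apoptosis list no longer passed (adjusted p = 0.101).

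Effector cytokine transcripts were lower in 10 of 13 members, with a median of -0.62 (camera adjusted p = 0.00451, and adjusted p = 0.585 with an estimated correlation). No tested member passed over all genes without the block, 6 were lower when adjusted over the list alone, and 6 passed over all genes with the block. IFNG, the main type 1 effector cytokine, was at 12.23 ± 0.43 with IL-2 and 11.01 ± 0.68 with IL-2 + IL-10, a difference of -1.22 (adjusted p = 0.152, 0.00918 with the block). TNF differed by -1.11 (adjusted p = 0.194, 0.0158 with the block), LTA, encoding lymphotoxin alpha, by -1.98 (0.108 and 0.00932) and IL4 by -1.78 (0.117 and 0.00403). The medians in the 3 numbers were -0.77, -0.16 and -0.93, and without IL-2 replicate 1 the median was -0.24 (adjusted p = 0.0133). The list's call was lost without IL-2 + IL-10 replicate 3 (median -0.26, adjusted p = 0.103), without genes that other lists hold (0.167) and without the filter on low values (median -0.095, adjusted p = 0.140). Transcripts of IL2 and IL10 lay below the expression filter on all 6 arrays, IL10 at 3.64 ± 0.09 with IL-2 and 4.28 ± 0.56 with IL-2 + IL-10. CSF2, also on this list, had no probe set with a single gene symbol and was not analysed here.

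Chemokine ligands were lower in 6 of 7 tested members, with a median of -0.85 (camera adjusted p = 0.000235, and adjusted p = 0.353 with an estimated correlation). CCL1 fell over all genes, 5 members were lower when adjusted over the list alone, and 5 passed over all genes with the block. With CCL1 floored at the 40th percentile its difference did not pass (-0.77, adjusted p = 0.0524), nor did the list under a filter at the 60th percentile (adjusted p = 0.0575). XCL1, which attracts dendritic cells, was at 13.10 ± 0.57 and 11.40 ± 0.53 (difference -1.70, adjusted p = 0.0806, 0.00403 with the block, 0.0492 without IL-2 replicate 1), CCL4 differed by -0.85 (0.115 and 0.0118) and CCL20 by -1.39 (0.202 and 0.0101). The probe set of XCL1 is of a kind that can also detect related transcripts, such as XCL2. The type 17 list, of 4 tested genes that were all lower (median -0.65, camera adjusted p = 0.00967), lost its call with an estimated correlation (adjusted p = 0.585) and without the filter (0.271), and without IL-2 + IL-10 replicate 1 its median was -0.36 (0.0377). None of its members passed over all genes, 3 were lower when adjusted over the list alone, and 2 passed with the block, CCL20 and AHR (-0.57, adjusted p = 0.209 and 0.0177). The type 2 cytokine list had a small median of -0.09, with 9 of 11 members lower (camera adjusted p = 0.0131, and adjusted p = 0.585 with an estimated correlation). CCL1 fell, 3 members were lower when adjusted over the list alone, and IL13 differed by -1.22 (adjusted p = 0.101, 0.0118 with the block). Without IL-2 + IL-10 replicate 1 the type 2 median was -0.18 (adjusted p = 0.00232). The type 2 call was lost without IL-2 replicate 1 (adjusted p = 0.174), IL-2 replicate 2 (0.0926) or IL-2 + IL-10 replicate 3 (0.113), without genes that other lists hold (0.676) and with the 60th percentile filter (0.354).

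The IL-10 and STAT3 pathway was the 1 list that was higher. Of its 20 tested members 16 were higher, with a median of 0.25 (camera adjusted p = 0.00173, and adjusted p = 0.353 with an estimated correlation). Without IL-2 + IL-10 replicate 2 the median was 0.14 (adjusted p = 0.0112). FURIN, SOCS3, the metalloproteinase inhibitor TIMP1 (0.98) and SBNO2 (0.84) rose, and the same number, 4, was higher when adjusted over the list alone. TIMP1 and SBNO2 did not pass without the filter on low values (adjusted p = 0.0516 for each), nor SBNO2 after a second quantile normalization (0.0514). BCL6, a transcriptional repressor, differed by 1.20 (adjusted p = 0.307, 0.00851 with the block). The receptor chains and STAT3 did not pass in either model: IL10RA differed by 0.09 (SE 0.18), IL10RB by 0.16 (SE 0.09) and STAT3 by 0.29 (SE 0.18). The IL-2 and STAT5 list did not pass (median -0.13, camera adjusted p = 0.0813, but 0.0162 with the 60th percentile filter, 0.0343 without IL-2 + IL-10 replicate 1 and 0.00794 without IL-2 + IL-10 replicate 2, and adjusted p = 0.858 with an estimated correlation over all 6 arrays), while NAMPT (-0.80) and BCL2L1 in it fell and TNFRSF8, or CD30, rose by 0.70, with 2 higher and 5 lower when adjusted over the list alone.

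**Figure D2:**
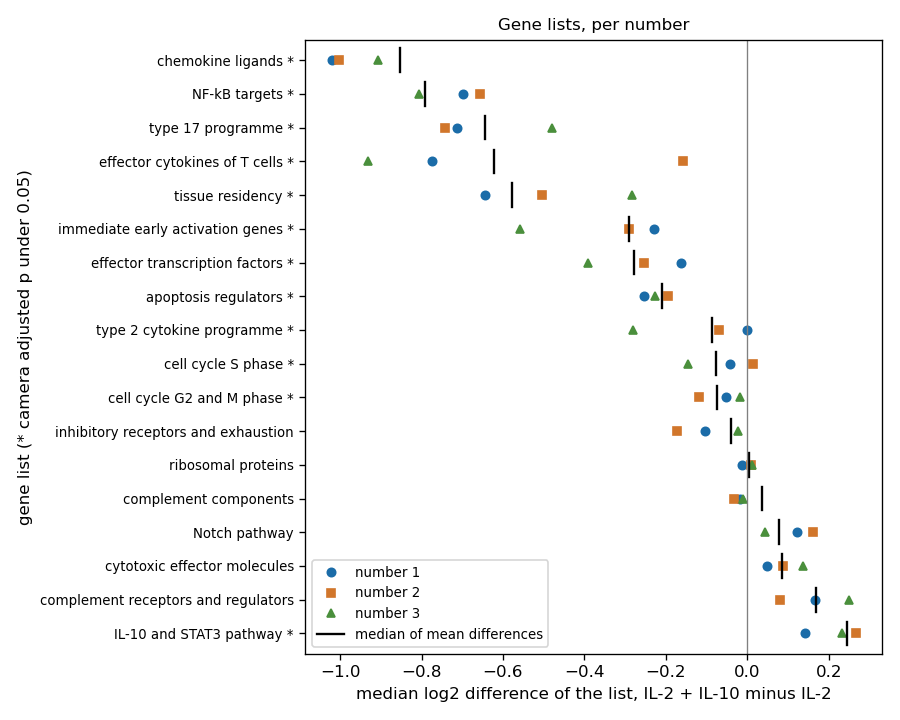
Median log2 difference of gene lists between the IL-2 + IL-10 and the IL-2 array of each number (symbols) and over the mean differences (black lines), for lists that passed camera with a preset correlation (asterisks) and 6 others. Chemokine ligands (-0.85) and NF-kB targets (-0.79) have the lowest medians and the IL-10 and STAT3 pathway the highest, 0.25.

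Cytotoxic effector molecules did not pass as a list (median 0.09, camera adjusted p = 0.476), and its members went both ways. GZMB, encoding granzyme B, was at 13.56 ± 0.18 with IL-2 and 14.11 ± 0.07 with IL-2 + IL-10, a difference of 0.54 (adjusted p = 0.0722, 0.0231 with the block), close to the arrays' highest values, 14.22 to 14.26. PRF1, encoding perforin, differed by 0.47 (0.116 and 0.0360) and GNLY, encoding granulysin, by 0.89 (0.194 and 0.0154). The death ligands lay on the other side, TNFSF10 at -0.92 (0.285 and 0.0211) and FASLG at -0.46 (0.447 and 0.0399). With trend and robust settings in eBayes GZMB passed (adjusted p = 0.0366). GZMA (0.16, SE 0.14) and GZMK (-0.06, SE 0.23) passed in neither model. No member passed over all genes without the block, 2 were higher when adjusted over the list alone, and with the block 3 were higher and 2 lower.

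Among inhibitory receptors (median -0.04, camera adjusted p = 0.568), CTLA4 (0.93) and CD244 (0.96) rose and NR4A3 fell, with 3 higher and 6 lower when adjusted over the list alone. LAG3 differed by 0.45 (adjusted p = 0.168, 0.0485 with the block). The probe set of CTLA4 is likewise of a kind that can detect other transcripts. PDCD1, HAVCR2 and TIGIT were not analysed here. NK-type receptors of T cells (median -0.41, camera adjusted p = 0.154) included the rise of CD244 and the fall of CRTAM, with 1 higher and 3 lower when adjusted over the list alone. Among costimulatory receptors (median -0.03, camera adjusted p = 0.598), TNFRSF8 rose, 1 was higher and 3 lower when adjusted over the list alone, and TNFRSF9, or 4-1BB, was at 11.05 ± 0.52 with IL-2 and 9.55 ± 0.56 with IL-2 + IL-10, a difference that did not pass without the block and passed with it (adjusted p = 0.00940). The chemokine receptor list did not pass (median -0.05, mean 0.11, a test in the lower direction, camera adjusted p = 1.00), with CCR1 higher and CX3CR1 lower, and with 3 higher and 2 lower when adjusted over the list alone.

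Complement lists did not pass. Of the complement components, 7 were tested (median 0.03, mean 0.09, a test in the lower direction, camera adjusted p = 1.00), none passed in either model or when adjusted over the list alone, and C3 was at 6.27 ± 0.19 with IL-2 and 6.02 ± 0.05 with IL-2 + IL-10 (adjusted p = 0.292). C5 and C5AR1, the receptor of the C5a fragment, lay below the filter on all 6 arrays. Among complement receptors and regulators (median 0.17, camera adjusted p = 0.306), CLU rose, and 3 were higher and 2 lower when adjusted over the list alone. C3AR1, the receptor of C3a, differed by 0.37 (SE 0.11, adjusted p = 0.149). CD59, which blocks the membrane attack complex, differed by -0.85 (adjusted p = 0.139, 0.00795 with the block), with all 4 of its probe sets lower. CD55 (-0.41, SE 0.14) and CD46 (-0.19, SE 0.10) passed in neither model, and 1 of the 3 probe sets of CD46 was higher. The Notch list did not pass (median 0.08, camera adjusted p = 0.284, 3 higher and 1 lower when adjusted over the list alone), and NOTCH1 differed by 0.43 (adjusted p = 0.121, 0.0344 with the block).

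Effector transcription factors were lower in 9 of 13 members, with a median of -0.28 (camera adjusted p = 0.0241, and adjusted p = 0.664 with an estimated correlation). ZEB2, a factor of terminal effector cells, fell by 0.81 (adjusted p = 0.0482, 0.0516 without the filter), 3 were lower and 1 higher when adjusted over the list alone, and IRF4 differed by -0.92 (adjusted p = 0.0655, 0.0177 with the block, 0.0446 without IL-2 + IL-10 replicate 3) and TBX21, encoding T-bet, by -0.43 (adjusted p = 0.423). EOMES was not analysed here. The call was lost without IL-2 replicate 2 (adjusted p = 0.0926) or IL-2 + IL-10 replicate 3 (0.0843), and without IL-2 + IL-10 replicate 1 the median was -0.15 (0.0377). The tissue residency list was lower in 7 of 11 members, with a median of -0.58 (camera adjusted p = 0.0406, and adjusted p = 0.585 with an estimated correlation). CD69 and CRTAM fell, 6 were lower and 2 higher when adjusted over the list alone, and CXCR6, which marks resident cells, differed by 0.89 (adjusted p = 0.107, 0.0108 with the block). Without genes that other lists hold, its median was 0.0034 (adjusted p = 0.793), and the call was also lost without IL-2 + IL-10 replicate 1 (0.0742), IL-2 replicate 2 (0.136) or IL-2 + IL-10 replicate 3 (0.103). Without IL-2 + IL-10 replicate 2 the median was -0.37 (0.0112). Memory and naive T cell genes (median 0.20, camera adjusted p = 0.598, 1 higher and 1 lower when adjusted over the list alone) and T cell receptor genes (median 0.08, camera adjusted p = 0.173) did not pass, and in the latter 4 members were higher when adjusted over the list alone, among them LAT at 0.77 (adjusted p = 0.0591, 0.0303 with the block, 0.0473 after a second quantile normalization, 0.0461 with centring, 0.0391 with the mean of probe sets and 0.0385 without IL-2 + IL-10 replicate 1).

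Cell cycle lists had small medians below 0. S phase genes had a median of -0.08 with 28 of 34 lower (camera adjusted p = 0.0406, and adjusted p = 0.858 with an estimated correlation), and 1 was lower when adjusted over the list alone. G2 and M phase genes had a median of -0.07 with 24 of 36 lower (camera adjusted p = 0.0452, 0.0733 with the block, and adjusted p = 0.585 with an estimated correlation), and none passed when adjusted over the list alone. MKI67, a marker of proliferating cells, was at 10.08 ± 0.09 and 9.77 ± 0.23 (adjusted p = 0.288). The S phase medians in the 3 numbers were -0.043, 0.013 and -0.15. The S phase call was lost without IL-2 replicate 1 (median -0.021, adjusted p = 0.442), IL-2 + IL-10 replicate 2 (0.0869) or IL-2 + IL-10 replicate 3 (median -0.019, adjusted p = 0.719), and without IL-2 + IL-10 replicate 1 the median was -0.16 (adjusted p = 0.000731). The G2 and M phase call was lost without IL-2 replicate 1 (0.148) or 2 (0.137) or IL-2 + IL-10 replicate 2 (median -0.048, adjusted p = 0.184) or 3 (0.178). Both were also lost without genes that other lists hold (adjusted p = 0.0637 for each), with the 60th percentile filter (0.0575 for S phase and 0.0622 for G2 and M phase) and after a second quantile normalization (0.0812 and 0.157). The G2 and M phase call was lost as well without the filter (0.0519) and with the mean of probe sets (0.0718).

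Glycolysis and hypoxia genes were higher in 19 of 23 members (median 0.09, camera adjusted p = 0.0813, 0.0480 after a second quantile normalization, 0.0397 without IL-2 replicate 3, 0.0330 without IL-2 + IL-10 replicate 3, and 0.0387 with the block, a call lost at adjusted p = 0.761 with an estimated correlation), with 3 higher and 2 lower when adjusted over the list alone. PFKFB3, an activator of glycolysis, differed by 0.96 (adjusted p = 0.115, 0.0177 with the block, 0.0361 without IL-2 + IL-10 replicate 1) and the glucose transporter SLC2A3 by 0.76 (0.127 and 0.0177). The remaining programme lists did not pass. Oxidative phosphorylation had a median of 0.02 (camera adjusted p = 0.568), cholesterol synthesis -0.02 (0.652), heat shock -0.07 (0.598), the type I interferon response 0.03 (0.864) and the interferon gamma response -0.03 (0.598). Antigen presentation had medians of -0.01 for class I (0.924) and 0.08 for class II (0.652). Unfolded protein and amino acid stress had a median of -0.01 beside a mean of 0.09 and a test in the higher direction (0.700), and ribosomal proteins a median of 0.0042 beside a test in the lower direction (0.949). Of the members of these lists DDIT4, in the stress list, alone passed over all genes without the block. With the block, 4 type I interferon genes were higher and 1 lower, 1 interferon gamma response gene was higher and 2 lower, 1 heat shock gene was higher and 1 lower, and 1 class II gene was higher. Among them were OASL (0.49, adjusted p = 0.121, 0.0275 with the block, 0.0336 with the mean of probe sets) and DNAJA1 (-0.42, adjusted p = 0.0626, 0.0262 with the block, 0.0389 with trend and robust settings). When adjusted over the list alone, 2 stress genes, 2 heat shock genes, 1 interferon gamma response gene and 1 class II gene were higher and 1 heat shock and 1 interferon gamma response gene lower.

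None of the tested lists of other cells' markers passed camera, with or without the block. The plasma cell list passed directional fry with the block (adjusted p = 0.0440). Mixed fry without the block called some of these lists, among them B cells (0.00243) and CD4 T cells (0.00334). Of 18 monocyte and macrophage markers 2 were above the filter, and the median level of the 18 was 4.27 with IL-2, below the 25th percentile of every array. Regulatory T cell and granulocyte or mast cell lists also had fewer than 4 tested members, 3 in each. Camera's adjusted p was 0.652 for B cells, 0.750 for both CD4 T cells and NK and gamma delta T cells, 0.949 for plasma cells, 0.306 for erythroid cells and platelets, 0.829 for fibroblasts and endothelium, and 1.00 for dendritic cells and for epithelial and tumour cells. Median and mean differed in sign for plasma cells (-0.09 and 0.09), dendritic cells (0.02 and -0.04, with a test in the higher direction), epithelial and tumour cells (0.02 and -0.06) and fibroblasts and endothelium (0.03 and -0.04). When adjusted over the list alone, 1 gene each was higher in the B cell, plasma cell, epithelial, regulatory T cell and CD4 T cell lists, and 1 lower in the last. CTLA4, in the CD4 T cell and regulatory T cell lists, rose with IL-2 + IL-10, as did PAX5 (0.88), a B cell transcription factor, while the B cell genes CD79A (-0.26, SE 0.26) and CD79B (-0.02, SE 0.12) did not pass. PAX5 was called from 1 of its 2 probe sets, the other lying below the filter, and its difference was 0.61 with low values set to the 40th percentile (adjusted p = 0.0385). Single markers of other cells passed over all genes with the block and not without it. KIT, in the granulocyte and mast cell list, differed by -0.54 (adjusted p = 0.389, 0.0156 with the block), the keratin KRT7 of epithelial cells by -0.69 (0.408 and 0.0457), TNFRSF4, in the CD4 T cell list, by -0.63 (0.136 and 0.0319, and 0.0485 without IL-2 replicate 1), and MZB1, in the plasma cell list, by 0.69 (0.107 and 0.0158, and 0.0492 without IL-2 replicate 1). GNLY, which also passed with the block alone, is in the NK and gamma delta list too.

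The 3 numbered pairs moved alike for many genes. All 3 differences had the same sign in 3773 of 7983 genes, or 47.3%, against 25% from chance, 2177 of them higher and 1596 lower. Correlations of the differences across genes, which are not independent replicates, were 0.76 between numbers 1 and 2, 0.47 between 1 and 3 and 0.53 between 2 and 3. The median difference over all tested genes was 0.01. EMP1, with a difference of 2.11, showed how far levels varied between numbers, with SDs of 1.07 and 0.84 within the groups (adjusted p = 0.143, 0.0117 with the block).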

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

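The tests of monocytes or macrophages, dendritic cells, NK or gamma delta T cells and AU-rich mRNAs were chosen after the results they bear on were seen, and those of RNA quality, normalization and other groupings of the arrays before.

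Among the 1587 tested probe sets without a single gene symbol, which no gene comparison used, 4 were higher and 2 lower in IL-2 + IL-10 at adjusted p under 0.05 when every probe set was its own row. They are listed because they lie outside the gene comparison, with 4 above the level in the IL-2 arrays. They were no larger a share than among all 13427 tested probe sets, of which 104 passed. With the block, 64 passed, 44 higher and 20 lower, against 638 of all sets. The lower set with the larger difference was at 10.42 ± 0.13 with IL-2 and 8.49 ± 0.55 with IL-2 + IL-10 (adjusted p = 0.0302). The higher set with the smallest p was at 7.91 ± 0.09 with IL-2 and 8.65 ± 0.10 with IL-2 + IL-10 (adjusted p = 0.0237). None of these sets was assigned to a gene. Genes without a single-symbol set, such as CSF2 on the cytokine list or the untested members of the NF-kB list, could lie among them.

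The 88 called genes and 12 called lists were set against other groupings of the same arrays. Among the 10 splits into 3 and 3, the others gave at most 0 genes and up to 10 lists, so 1 split, the real one, reached the real number in each case. The split with 10 lists put both arrays of number 1 on 1 side and both of number 2 on the other, and so set these numbers against each other. The other splits that, like the real one, parted all 3 pairs gave 0 genes and 1 to 5 lists. At an unadjusted p under 0.05 these gave 19 to 257 genes, the remaining splits up to 964, and the real one 1362. With the block, exchanging the treatment within numbers gave at most 0 genes in the others of the 4 arrangements, against 528, and 1 arrangement, the real one, reached that number. At an unadjusted p under 0.05 the other arrangements gave 35 to 466 genes, against 1980. So few groupings cannot give a share under 0.05.

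NF-kB target genes had a median of -0.79 over 15 members and were lower in the camera test with a preset correlation, a call lost at adjusted p = 0.585 with an estimated correlation. A shift with expression level from the authors' normalization is argued against, since 0% of 10000 random lists matched on mean expression had a median as low, the lowest being -0.23, and fewer monocytes or macrophages are argued against by the median marker level of 4.27 on the IL-2 arrays. Fewer dendritic cells, which the negative selection for CD8+ cells is meant to remove, stay open, since their markers' median level, 5.50, lay near the filter and decides nothing. RNA quality stays open by a narrow margin: the paired difference between 3' and 5' probe sets had a mean of 0.026 for ACTB, with no common sign in the 3 numbers, and its 95% interval, -0.464 to 0.517, went just beyond the bound of 0.5, while that of GAPDH, -0.074 to 0.102, lay within it. The treatment itself, which the design names, also stays open, with no test here that would single it out.

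The granule genes PRF1, GZMB and GNLY, which passed with the block but not in the same model without it, had a median difference of 0.54 beside cytokine genes with a median of -0.62. These 3 were picked from 16 tested members of the cytotoxic list, 11 higher and 5 lower. That whole list had a median of 0.09 (camera adjusted p = 0.476), so the contrast rests in part on the choice of genes. The cytokine median was -0.24 without IL-2 replicate 1, and camera's call for that list was lost with an estimated correlation (adjusted p = 0.585). A larger share of NK or gamma delta T cells, which the same negative selection is meant to remove, stays open: the 4 tested markers outside the granule and cytokine lists had medians of at most 0.059 in any number, but 0 of them lay more than 1 above the filter level, so a small share could be missed. NK-type receptors that T cells also carry leaned against a larger share, with 7 of 11 lower, 4 higher and a median of -0.41. Their list did not pass camera (adjusted p = 0.154, and 0.585 with an estimated correlation). Among the lower were KLRD1 (-0.41), KLRB1 (-0.72, adjusted p = 0.536, 0.0552 with the block) and NCR3 (-0.47, adjusted p = 0.102, 0.0245 with the block). The level of these receptors in T cells would hide a small share, and CD244 rose. A loss of mRNAs with AU-rich ends in general also stays open: immediate early genes outside those lists had a median of -0.29, just short of the -0.31, set from the cytokine median, that this explanation needed and beyond the bound set against it, but without IL-2 replicate 1, IL-2 + IL-10 replicate 2 or IL-2 + IL-10 replicate 3 their median (-0.30, -0.41 and -0.18) passed the value needed there (-0.12, -0.34 and -0.13). An effect of the treatment on the same cells stays open too and was not tested apart from a change in the mix of cells.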

How the results depend on the processing

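No alternative in this part was chosen after the results were seen. The 88 genes became 528 with the number as a block, 234 at an adjusted p under 0.10 and 2 in the unmoderated model. Without the block, 0 to 66 genes passed when arrays or numbers were left out. With the block, 70 to 1524 passed when a number was left out, against 528. At an unadjusted p under 0.05, the 1362 genes became 252 with a difference of at least 1.5-fold and 278 with that and the block. They became 606 to 1664 when arrays or numbers were left out without the block. With the block, 1980 genes became 1136 to 2720 when a number was left out. The other filters, scalings, summaries and the 1.5-fold minimum at the adjusted threshold gave 74 to 104 genes. The 12 lists became 0 with an estimated correlation, 4 without genes that other lists hold, 7 to 13 when arrays or numbers were left out, and with fry 2, or 7 with the block, and in its mixed form 23, or 33 with the block. The 2 lists that passed directional fry without the block were apoptosis regulators (adjusted p = 0.0150) and the IL-10 and STAT3 pathway (0.0183). Chemokine ligands and the type 17 list had too few members left for the test without shared genes. The share of genes with 1 sign in all 3 numbers was 40.3% without a filter, 50.8% with the 60th percentile filter and 48.4% with the mean of probe sets, against 47.3%. Of the 183 genes under the naming rule, the 34 that passed also passed with the block and 61 more passed with it. The block ended the call of G2 and M phase genes, added glycolysis and hypoxia, and changed no other list call. Apart from the other thresholds, which set their counts by construction, the cause of these changes was not tested.

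Direction changed 132 times, for 25 genes and 18 lists, and 1 of these had an adjusted p under 0.05 in either setting, tissue residency without shared genes. With a second quantile normalization the difference was -0.0073 for CD1C, -0.0095 for CD22, 0.0092 for IL2RA and -0.0095 for B cells. With the floor the difference was 0.0013 for IGHG1. With the mean of probe sets the difference was 0.012 for HLA-DOA, 0.050 for HLA-F, -0.022 for PECAM1, 0.11 for chemokine receptors and 0.0063 for interferon gamma response. With the 60th percentile filter the difference was 0.35 for chemokine receptors, 0.020 for inhibitory receptors and exhaustion and 0.029 for unfolded protein and amino acid stress. Without shared genes the difference was 0.033 for inhibitory receptors and exhaustion, 0.0034 for tissue residency and 0.059 for interferon gamma response. With centring the difference was -0.0028 for ribosomal proteins. Without a filter the difference was 0.012 for CD4 T cells and -0.046 for NK and gamma delta T cells. Over the settings without arrays, gene differences ran from -0.0054 to 0.52 for CCL22, -0.026 to 0.099 for CD1A, -0.10 to 0.099 for CD22, -0.11 to 0.086 for CD79B, -0.070 to 0.21 for FCER1G and -0.21 to 0.22 for GZMK. Other genes ran from -0.32 to 0.28 for HBB, -0.35 to 0.17 for IGHM, -0.055 to 0.15 for THY1, -0.022 to 0.071 for COL1A1, -0.20 to 0.00058 for HLA-F and -0.059 to 0.25 for IL10RA. Other genes ran from -0.14 to 0.086 for TPSAB1, -0.12 to 0.021 for NCAM1, -0.017 to 0.034 for CD1C, -0.034 to 0.11 for SFTPB, -0.98 to 0.0057 for LAMP3 and -0.15 to 0.0041 for ALAS2. Other genes ran from -0.22 to 0.037 for CCR4, -0.11 to 0.0063 for IGKC, -0.18 to 0.16 for IL2RA, -0.0013 to 0.088 for PECAM1 and -0.24 to 0.034 for TAP1. Among lists, medians ran from -0.093 to 0.037 for chemokine receptors, -0.21 to 0.082 for costimulatory receptors, -0.013 to 0.27 for memory and naive T cells, -0.12 to 0.19 for type I interferon response and -0.10 to 0.024 for interferon gamma response. Further lists ran from -0.028 to 0.014 for antigen presentation class I, -0.026 to 0.13 for antigen presentation class II, -0.092 to 0.020 for cholesterol synthesis, -0.15 to 0.16 for unfolded protein and amino acid stress and -0.0068 to 0.021 for ribosomal proteins. Further lists ran from -0.17 to 0.037 for CD4 T cells, -0.070 to 0.048 for B cells, -0.013 to 0.066 for dendritic cells, -0.051 to 0.086 for epithelial and tumour cells and -0.023 to 0.037 for fibroblasts and endothelium. The number of arrays limits the precision of all these values.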

Other observations

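No test in this part was chosen after its result was seen, and the values below are given without explanation.

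Several genes not described above differed by more than 2-fold as measured and passed with the number as a block but not in the model without it. CEBPD, a transcription factor of acute responses, differed by 1.59 (adjusted p = 0.0655, 0.0173 with the block), LY96, a partner of the endotoxin receptor, from 5.91 ± 0.44 to 7.41 ± 0.56 (0.0873 and 0.0319), the laminin receptor chain ITGA6 by 1.41 (0.0923 and 0.0108) and ITGAX, or CD11c, a chain of complement receptor 4, by 1.21 (0.127 and 0.0458). On the lower side were RGS16 at -1.77 (0.0775 and 0.00940), TNIP3 at -1.51 (0.256 and 0.00458), the pro-apoptotic BCL2L11 at -1.46 (0.107 and 0.0141) and the costimulatory ligand TNFSF4 at -1.40 (0.273 and 0.00528). All 3 numbers had these directions, which passing with the block makes likely. ITGA6 lay under the 40th percentile on every IL-2 array, and with values under that percentile set to it, its difference was 0.72 (adjusted p = 0.193), less than 2-fold, beside 1.45 for CEBPD (0.0733), 1.47 for LY96 (0.0859) and -1.31 for TNIP3 (0.245). Without the block, leaving out 1 array brought 3 of them past the threshold: BCL2L11 without IL-2 replicate 1 (adjusted p = 0.0371), CEBPD without IL-2 + IL-10 replicate 1 (0.0332) and ITGAX without IL-2 + IL-10 replicate 3 (0.0267). IRF8, at 8.84 ± 1.12 with IL-2 and 7.34 ± 0.61 with IL-2 + IL-10, passed in neither model (adjusted p = 0.241, 0.0618 with the block).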
